A study of Mus musculus with 16 samples.

How the data were processed

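Genomic DNA from the tails of 8 C57BL/6 mice of a single family, a sire, a dam and 6 progeny, was hybridised against the DNA of a reference male on 2-colour Agilent comparative genomic hybridisation arrays. Each animal was measured on 2 arrays with the dyes exchanged, which gives 16 arrays. The labels give each animal its dye and its place in the family. The series title names males that received gamma rays at 1 mGy per day over 400 days, while the series text calls the parents of this family unirradiated, so no comparison of exposed with unexposed animals was made here. The reference male carries the number 8 in the sample titles and 7 in the channel labels, and the arrays were treated as sharing a single reference, as the series text says. The sex of the progeny is not in the labels and was not used to group animals.

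The arrays were scanned and quantified by the authors with Agilent Feature Extraction 10.7.1.1, per the file headers, with probe positions on the mouse build mm9. The processed signals are fluorescence intensity values on a linear scale that are already background-subtracted and dye-normalised, per the file headers. The deposited log10 ratio of each spot is that of Cy5 over Cy3. The deposited series table holds log2 values, and its comparison with the scanner values of each array gave a correlation of 0.992 or more in size. Its sign was that of reference over animal on every array, so it was turned before use. Its column medians lay between -0.01 and 0.01, and how it was centred is not given in the sources used here.

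The log2 ratio of the processed signals was turned to animal over reference from the dye labels, each array was centred on the median of its autosomal probes, and the 2 arrays of an animal were averaged to 1 value per animal. No loess or quantile step was used, since copy number changes can shift many probes one way. Control spots, spots flagged as non-uniform or as population outliers, and probes not well above background in both channels were left out. Repeated spots of a probe were averaged. Each array held 973116 spots, of which 966371 were not controls. The X chromosome had only 68 probes and the Y chromosome 23.

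Aberrant segments were called on the 19 autosomes of each animal with an exact least-squares fit of constant pieces, with a penalty of 20 times the noise variance per breakpoint. A call needed at least 3 probes, a mean and a median at least 0.25 from 0 on the log2 scale, and a mean of at least 0.25 in the same direction on each array of the pair. Background calls were counted with the same settings on a difference profile, the difference of the 2 arrays of an animal divided by 2 after the mean of the same quantity in the other animals was removed. Copy number cancels in that profile, and so do probe effects common to both dyes, so it is a background for noise of single arrays and not for effects shared by them. Calls that overlapped by at least 1 bp were merged into regions, and an animal was said to carry a region when its mean over the region's probes reached 0.25 in the called direction in the pair mean and on each array. Up to 10 regions per carrier class, ranked by their number of probes, were named, a rule fixed before the data were examined.

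Segment counts of progeny and parents were compared with an exact permutation test, two-sided. Probe values were tested with limma on 1 value per animal, with Benjamini-Hochberg adjustment, a threshold of 0.05 and a minimum effect of 0.25, over the 945109 autosomal probes measured in all 8 animals. The animals are relatives, so the p-values measure the spread between members of this family. Arrays were scanned on 4 days. The sire and dam shared a day and each other day held a pair of progeny, so scan day was also fitted as a random block with duplicateCorrelation.

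The callers were tested on simulated data. Segments planted in the difference profiles, 80 for each size and amplitude over the 8 animals, were recovered in 50% of cases at 3 probes and -0.40, in 80% at 5 probes and -0.40, in 97.5% at 10 probes and -0.40, and in 97.5% at 3 probes and 0.58. For the family against the reference, limma recovered 50% of the changed probes at an effect of 0.25 and 100% at 0.5, with 1 false call, in a run on 20000 probes. For progeny against parents it recovered 18% at 0.25, 70% at 0.5, 98% at 1 and 100% at 2. All effects were planted in a single run on 20000 probes, with 7 false calls in total beside 9, 35, 49 and 50 recovered probes.

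The alternatives fixed in advance were normexp background correction with an offset of 50, the series table in place of the scanner signals, no filter on dim probes, breakpoint penalties of 10 and 40, amplitude thresholds of 0.15 and 0.40, a minimum of 5 probes, an interval-score caller with a minimum score of 6, subtraction of a running median over 501 probes, no requirement of agreement between the arrays, merging at 50% overlap, each dye orientation alone, and leaving out each animal in turn. Normexp was run on the median spot signals and median backgrounds, while the main values come from the processed signals. The normexp setting therefore changed both the input signal and the background correction, and their parts were not tested separately. Alternatives added after the data had been seen were a minimum of 10 probes, leaving out isolated probes called in the whole family, and leaving out progeny 1 and progeny 4 together.

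Gene-level tests, tests of gene lists and the naming of genes in regions were planned but not run. The probe columns used here give positions on mm9 without gene names, and the gene table used here is of another build. Regions are therefore given by position. The probes on unplaced contigs of chromosomes 1 and 3 were left out of all calls. The authors' second array screen and their quantitative PCR assays were not analysed here. The number of arrays per animal limits the precision of each value. Analyses used Python 3.11.15, NumPy, pandas, SciPy, Numba and, in R 4.3.3, limma 3.58.1.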

Results

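DNA copy number was profiled in a family of C57BL/6 mice, with the sire, the dam and 6 progeny each set against the same reference male of the colony. The design asks which copy number aberrations occur in the progeny and which of these are absent from both parents. Each animal had 2 arrays with exchanged dyes, 16 arrays in all, and between 947003 and 949713 autosomal probes were measured per animal. Signal over noise ranged from 36.9 to 67.3 in Cy3 and from 35.2 to 55.9 in Cy5. The noise SD of a probe's pair mean was 0.11 ± 0.01 on the log2 scale (SD, n = 8 animals), lowest in the dam at 0.10 and highest in progeny 4 at 0.12. All values below are log2 ratios of animal over reference, and the SD beside a region's value is over its probes unless stated otherwise.

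The X and Y chromosomes gave a check on the direction of the ratios, since the reference was a male. The dam had a median of 0.98 over 67 X probes (SD over probes 0.12). The sire had medians of 0.00 on X and -0.02 on Y. Progeny 5 had an X median of 0.98 and progeny 6 had 0.99. Of the 23 Y probes, 6 in the dam, 13 in progeny 5 and 7 in progeny 6 were not well above background on either array, so their Y ratios have only a bound. With each signal raised to at least the lowest signal well above background, the Y medians were -2.01 in the dam, -2.27 in progeny 5 and -1.73 in progeny 6, or at least 4.02-fold, 4.81-fold and 3.32-fold lower than the reference in the processed signals. With normexp they were -0.36, -0.37 and -0.36. Progeny 1, 2, 3 and 4 had X medians from -0.01 to 0.00 and Y medians from -0.02 to 0.01. The spread between the arrays of an animal, pooled over the 8 animals, was 0.02 for X and 0.17 for Y.

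**Figure D1:**
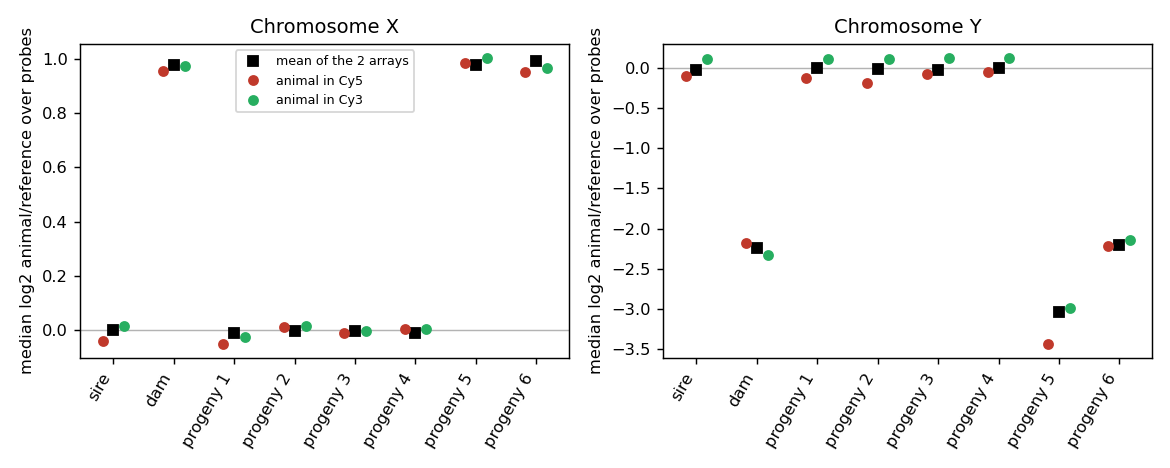
Median log2 ratio of animal over reference (vertical axes) over the probes of chromosome X (left) and Y (right) for each animal. Circles are the single arrays and squares are medians of the probes' pair means. On Y, the dam, progeny 5 and progeny 6 are drawn as measured, with probes not well above background included. The dam, progeny 5 and progeny 6 lie at 0.98, 0.98 and 0.99 on X, and the other 5 animals lie between -0.01 and 0.00.

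A gain of 160 kb on chromosome 4, from 101110482 to 101270535 on mm9, was carried by all 8 animals and was the region with the most probes, 74. It lay at 2 levels. The sire had a mean of 0.99 (SD 0.11, 74 probes), which is 1.98 times the reference, and progeny 4 had 0.97 (SD 0.11), or 1.95 times. The dam had 0.56 (SD 0.12), or 1.47 times, and progeny 1, 2, 3, 5 and 6 had 0.57, 0.57, 0.58, 0.56 and 0.52. The 2 arrays of an animal differed little, with 0.98 and 0.99 in the sire and 0.49 and 0.55 in progeny 6. The other 2 regions called as gains in all animals had 3 probes each. They lay on chromosome 10 from 97107277 to 97112535 with a mean of 0.62 ± 0.07 (SD, n = 8 animals) and on chromosome 13 from 95707465 to 95712034 with 0.59 ± 0.07 (SD, n = 8 animals). Both had an SD over their 3 probes between 0.78 and 1.13 in each animal, larger than the mean in every animal. In the limma test of the family against the reference, all adjacent probes called higher lay in the 160 kb gain on chromosome 4. Neither 3-probe region is therefore shown to be a gain over all of its probes. With normexp background correction the chromosome 10 mean fell to 0.09, under the threshold of 0.25, while that on chromosome 13 stayed at 0.58.

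**Figure D2:**
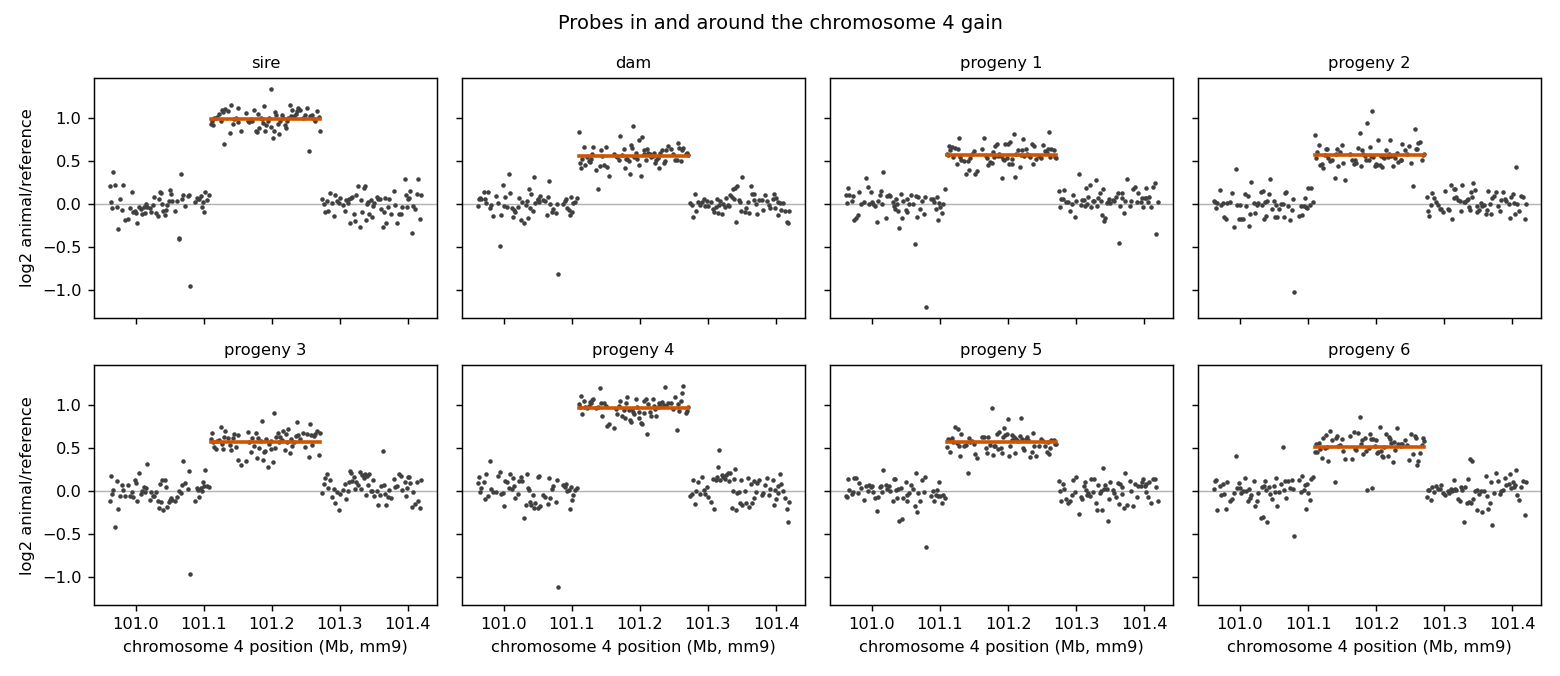
Log2 ratio of animal over reference (vertical axis) of single probes against their position on chromosome 4 in Mb (horizontal axis, mm9), 1 panel per animal. Dots are pair means of probes and the line is the mean over the 74 probes of the gain. The sire and progeny 4 sit at 0.99 and 0.97, and the other 6 animals sit between 0.52 and 0.58.

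Of the 634 regions, 90 were carried by at least 1 parent and at least 1 progeny but not by all animals, 6 of them gains and 84 losses. With normexp there were 24, and there were 36 when isolated probes called in the whole family were left out, a setting chosen after the data had been seen. Probe effects common to several animals cancel in the difference profiles, so these give no background for shared regions. In the sire's regions with the most probes the dam lay near 0. A loss of 56.3 kb on chromosome 4 from 78453216 to 78509511 (18 probes) was carried by the sire, progeny 1 and progeny 2 at -0.41, -0.43 and -0.41, and the other 5 animals lay between -0.05 and 0.04. A gain on chromosome 2 from 174991644 to 177826783, a span of 2835 kb covered by only 15 probes, was carried by the sire, progeny 3, progeny 5 and progeny 6 at 0.40, 0.39, 0.46 and 0.42, with the other 4 between -0.05 and 0.05. A loss on chromosome 17 from 13311524 to 13740075, 429 kb with 12 probes, was carried by the sire, progeny 1, progeny 2 and progeny 6 at -0.38, -0.39, -0.33 and -0.36. The other 4 animals lay between -0.08 and -0.01.

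A short stretch of chromosome 2 from 70079530 to 70085630 (4 probes) was bright in the sire, progeny 1, progeny 4 and progeny 6 on both of their arrays. The reference was not well above background at any of these probes on any array, nor were the dam, progeny 2, progeny 3 and progeny 5. The excess over the reference was therefore at least 5.89-fold in progeny 4, 6.39-fold in progeny 6, 6.74-fold in progeny 1 and 7.80-fold in the sire. On average over these animals it was at least 6.67-fold, from log2 2.74 ± 0.17 (SD, n = 4 animals), taken against, on each array, the higher of the reference's own signal and the lowest signal well above background. It was the only run of 3 or more autosomal probes bright in an animal and not in the reference, and 0 runs were bright in the reference and not in an animal. The bounds hold for the processed signals alone, since with normexp the mean log2 ratio of the 4 animals was 0.70. Mean log2 signal at these probes was 9.24 to 9.45 in the 4 bright animals, beside a median of 9.96 over all probes tested. It was 4.42 to 5.12 in the dam, progeny 2, progeny 3 and progeny 5. The bounds thus reflect a reference not well above background, not an unusually high signal in the bright animals, and give no number of copies.

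The 2 regions with the most probes among those with the dam as the carrier parent lay in the dam, progeny 5 and progeny 6, the 3 animals with an X median near 1. A gain of 128 kb on chromosome 8 from 102125282 to 102253497 (46 probes) had means of 0.28 in the dam, 0.27 in progeny 5 and 0.28 in progeny 6, and the other 5 animals lay between -0.09 and 0.01. Progeny 5 had 0.24 on 1 of its arrays and so was just short of the threshold for a carrier. A loss of 21.3 kb on chromosome 14 from 61798066 to 61819370 (13 probes) stood at -0.30, -0.35 and -0.41 in these animals, with an SD over probes from 0.31 to 0.35, and between 0.00 and 0.05 in the others. A loss on chromosome 3 from 25417435 to 25444229 (4 probes) stood at -1.48, -1.36 and -1.37 in the same animals, with an SD over probes from 0.60 to 0.77, and between -0.02 and 0.05 in the others. A 4-probe loss on chromosome 4 from 114577739 to 114585817 was carried by the dam and progeny 6 at -0.60 and -0.45, with the other animals between -0.24 and 0.12.

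In the remaining named regions of this class the other animals leaned the same way. The 7-probe loss on chromosome 19 from 46794891 to 46812142 stood at -0.31 in the sire and -0.39 in progeny 1, and between -0.18 and -0.09 in the other 6. The 5-probe loss on chromosome 9 from 109568596 to 109579434 stood at -0.37 ± 0.10 in the dam, progeny 1 and progeny 4 (SD, n = 3 animals), and at -0.22 ± 0.04 in the other 5 animals (SD, n = 5 animals). With normexp the carrier means of these 2 losses were -0.23 and -0.20, short of the threshold.

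**Figure D3:**
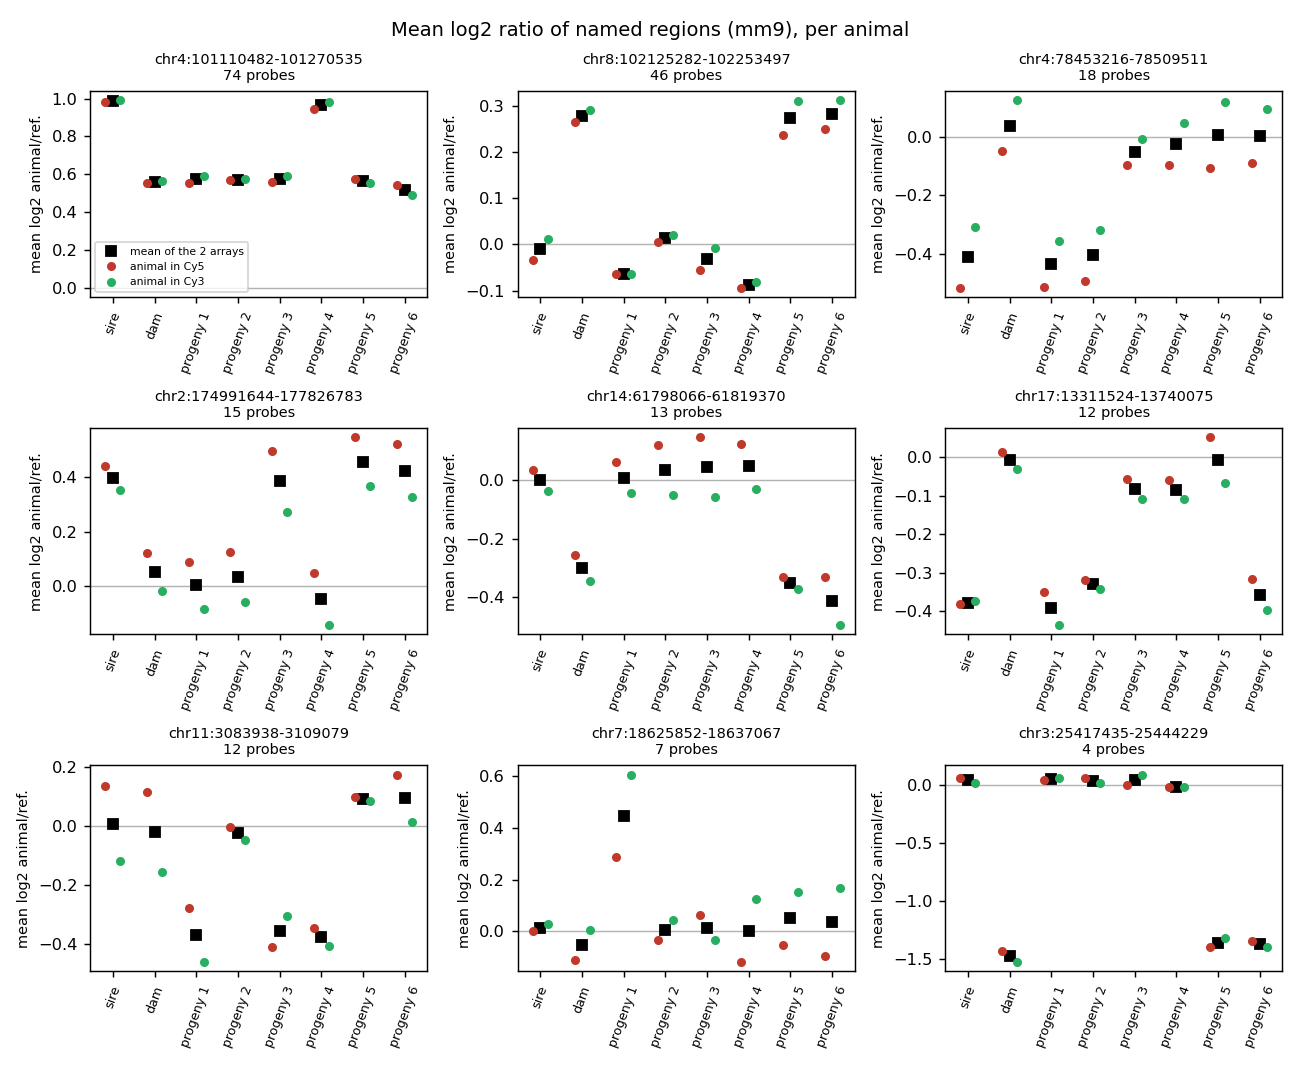
Mean log2 ratio of animal over reference (vertical axes) over the probes of 9 named regions for each animal, with positions on mm9 above each panel. Squares are means of the 2 arrays and circles are the single arrays. Of the regions shown, those on chromosomes 11 and 7 were carried by progeny only. The chromosome 7 gain stood at 0.45 in progeny 1 and between -0.05 and 0.05 in the other animals.

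Regions carried by progeny and by neither parent numbered 459, with 45 gains and 414 losses. The difference profiles gave 133. With normexp there were 49, and without progeny 1 there were 274. Regions whose carriers stood at least 0.25 apart from every other animal, a rule chosen after the data had been seen, numbered 119, against 125 in the difference profiles. Of the 459, 321 were carried by a single animal, 120 of them by progeny 1 and 83 by progeny 4, and the median length was 5150 bp. Only 37 had 5 or more probes, against 3 in the difference profiles, and 2 had 10 or more, against 0. The one with the most probes was a loss of 25.1 kb near the start of chromosome 11, from 3083938 to 3109079 (12 probes), at -0.37, -0.35 and -0.37 in progeny 1, 3 and 4. The SD over its probes was between 0.32 and 0.44. These progeny were also the animals with the most segments, at 260, 91 and 137, and whether that bears on this loss was not tested. The sire lay at 0.01, the dam at -0.02 and the other progeny between -0.02 and 0.09. After a running median along the chromosome was subtracted, the mean of the carriers was -0.18, short of the threshold. The only gain among the 10 named regions was on chromosome 7 from 18625852 to 18637067 (11.2 kb, 7 probes). It was carried by progeny 1 at 0.45 (SD 0.17, 7 probes), or 1.36 times the reference, with 0.29 and 0.61 on its arrays. The sire had 0.01 and the dam -0.05 there.

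Losses of 7 to 10 probes in progeny 4 alone made up most of the other named regions. The longest lay on chromosome 4 from 120916522 to 120968774 (52.3 kb, 10 probes) at -0.31 (SD 0.16), where progeny 1 had -0.20, the sire -0.02 and the dam -0.09. On chromosome 11 from 96237382 to 96257839 (8 probes) progeny 4 had -0.44 (SD 0.33), while the other 7 animals lay between -0.19 and 0.22, with the dam highest. On chromosome 13 from 119689676 to 119727925 (9 probes) progeny 4 had -0.29. An 8-probe loss on chromosome 1 from 64532326 to 64553029 was carried by progeny 1 and progeny 3 at -0.37 and -0.29. With normexp the chromosome 4 loss of progeny 4 was -0.19, that on chromosome 11 was -0.19 and that on chromosome 13 was -0.22. In all, 7 of the 10 named regions of this class had means short of the threshold with normexp. The chromosome 7 gain stood at 0.32 with that correction.

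Regions carried by a parent and by no progeny numbered 77, with 36 gains and 41 losses, and the difference profiles gave 36. There were 11 with normexp, and 305 and 9 with breakpoint penalties of 10 and 40. None had 10 probes. The one with the most probes was a 6-probe loss of the sire on chromosome 19 from 29262300 to 29272875 at -0.30 (SD 0.28). A 5-probe gain of the dam on chromosome 14 from 113769749 to 113782869 stood at 0.35 (SD 0.23). The means of all 10 named regions of this class fell short of the threshold with normexp.

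The number of autosomal segments did not differ detectably between generations. In total 760 segments were called, 648 of them losses, against 174 in the difference profiles. Only 63 had 5 or more probes, against 5 in the difference profiles, and the total varied widely with the caller's settings, as given below. Progeny 1 had 260 segments, progeny 4 had 137, progeny 3 had 91, progeny 2 had 53, progeny 5 had 47 and progeny 6 had 34. The sire had 66 and the dam 72. Progeny 1 and progeny 4 were also the animals whose neighbouring autosomal probes correlated most, at 0.0708 and 0.0875, against 0.00800 to 0.0196 in the other 6, and whether this raised their counts was not tested. The mean was 104 ± 85.3 in progeny (SD, n = 6) and 69.0 ± 4.24 in parents (SD, n = 2), a difference of 34.7 (exact permutation test, two-sided, p = 0.679, 28 splits, smallest possible p 0.0357). Without progeny 1 and progeny 4 the difference was -12.8, so its sign rested on these 2 animals. Segments of 10 or more probes numbered between 2 and 4 in every animal, 24 in total, and the difference profiles held 0.

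**Figure D4:**
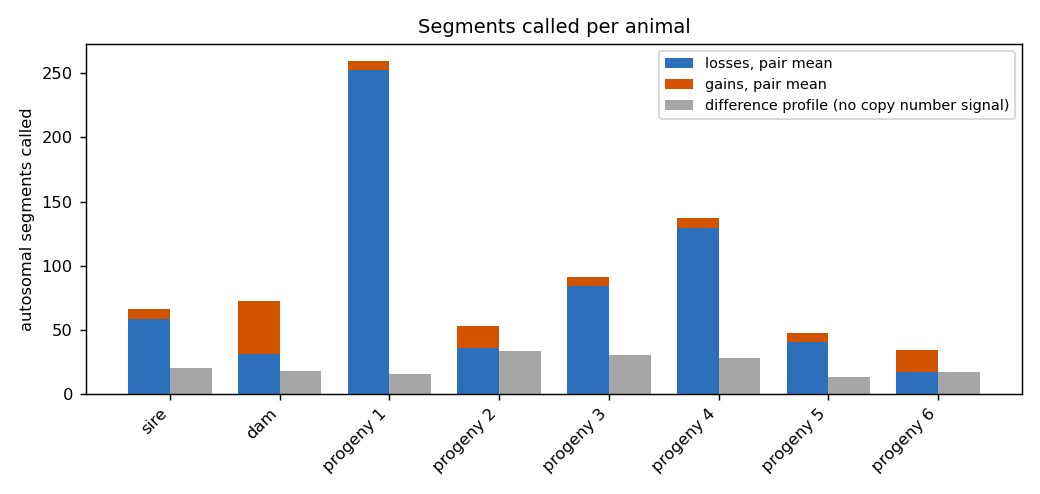
Autosomal segments called per animal (vertical axis, count), as losses and gains in the pair mean, beside the calls in the difference profile of the same animal, in which copy number cancels. Progeny 1 and progeny 4 had 260 and 137 segments in the pair mean and 15 and 28 in the difference profile.

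A copy number state of the reference alone would show in every animal, which the comparison of the family with the reference addresses. With limma, 6887 of 945109 autosomal probes differed from the reference, 256 higher and 6631 lower. With normexp the count was 4004, and at minimum effects of 0.15 and 0.40 it was 13444 and 2425. All 74 probes of the chromosome 4 gain were among the higher ones. The lower probes had a median effect of -0.35 and stood alone. Their nearest neighbours averaged -0.01 (SD 0.07, 13261 neighbours), and 58 pairs of lower probes were adjacent, against 46.5 by chance. All 73 adjacent pairs among the higher probes lay in the chromosome 4 gain, and the other 182 higher probes stood alone as well. The lower probes were spread over all autosomes, at 0.642% to 0.756% of the probes of each. They made up 1.68% of the dimmest 10% of probes and 0.143% of the brightest 10%. Their mean was lowest in progeny 1 at -0.53 and nearest to 0 in progeny 6 at -0.31.

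No autosomal probe differed between progeny and parents with limma at the adjusted threshold. That does not exclude differences in a few probes, since a probe with a difference of 0.96 was among those not called. An unadjusted p under 0.05 was found for 33283 of 945109 probes, a smaller share than the 0.05 that chance alone would give. Without the dam, 4 probes were called, all higher in progeny. Parents were scanned on a day of their own, so scan day and generation cannot be told apart. With scan day as a random block the count was 0 as well, which does not separate them.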

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

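All tests in this part were chosen after the results were seen. Of 41 sets of values over the 6 progeny, 4 held an animal set apart from the rest. Chance sets an animal apart in about 1 of 20 sets that were not selected, and no count by chance is given for these sets, because many are regions named for a call in an animal. The chromosome 4 gain from 101110482 to 101270535 stood at 0.97 in progeny 4, next to 0.58 in the nearest sibling. The chromosome 7 gain from 18625852 to 18637067 stood at 0.45 in progeny 1, next to 0.05. The chromosome 19 loss from 46794891 to 46812142 stood at -0.39 in progeny 1, next to -0.18. In the sire's region on chromosome 19 from 29262300 to 29272875, progeny 3 had -0.19, next to -0.05, which is short of the threshold for a carrier.

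The levels of the chromosome 4 gain argue against a reference male with a single copy, since 6 animals lay far from the log2 of a whole number of copies, by up to 0.48. A broad wave along the chromosome is argued against as well, since the mean over the 8 animals was 0.62 after a running median was subtracted and 0.66 before. A candidate explanation is a segregating duplication with 4 copies in the sire, 3 in the dam and 2 in the reference. With 2 copies on each of its 2 chromosomes, which was not measured, such a sire would pass on 2 copies to every progeny. The progeny lay within 0.068 of log2 0.58 or 1. It remains a hypothesis from a single family, and the order and place of the extra copies were not measured.

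The 3- and 4-probe losses of progeny 1 and progeny 4 numbered 240 and 118, beside 5 and 7 gains of that size. Random noise of single arrays is argued against in progeny 1, whose difference profile held 7 such losses in place of 240. In progeny 4 it held 18 in place of 118, which leaves noise open for part of them. Heterozygous deletions that halve the copy number are argued against too as the cause of the set. The median of these losses was -0.46 (SD 0.08) where a halved copy number gives -1, and 4 of them reached -0.75. Losses shared by the sire and progeny on chromosome 4 from 78453216 and chromosome 17 from 13311524 averaged only -0.42 and -0.36 in their carriers. The median therefore does not exclude losses of that kind. The 6 other animals averaged -0.16 (SD 0.11) over the losses of progeny 1 and -0.12 (SD 0.11) over those of progeny 4. The test first run left out the isolated probes called in the family comparison, and 80 and 73 losses stayed. Those probes were called partly on the values of progeny 1 and progeny 4 themselves, so that test decides nothing. A later test left out the 7120 probes with a mean of -0.25 or lower over the 6 other animals. In progeny 1, 53 of 240 losses stayed, against 231 to 242 after as many random probes were left out, which is consistent with probes that read low in the whole family and lowest in this animal. In progeny 4, 58 of 118 stayed, against 112 to 116. That met the limit first set by 1 loss and missed it once the range of the random draws was allowed for, a condition added after the count was seen, so progeny 4 stays undecided. The correlation of neighbouring probes, highest in these 2 animals, was not tested as a cause. Losses present in only part of an animal's cells were not tested and stay open.

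Among regions whose carriers, taken here from the pair mean alone, stood at least 0.25 apart from all other animals, 7 were carried by the dam and progeny but not the sire. Of these, 5 on 4 chromosomes had the same carriers, the dam, progeny 5 and progeny 6. Progeny 5 and progeny 6 were scanned on the same day and the dam on another, and scan day was not tested as a cause. With 0.25 also required on each array, as elsewhere, 5 of the 7 kept a carrier among the progeny and 4 of these, on 3 chromosomes, had the same carriers, since progeny 5 fell short in the chromosome 8 gain. If all 63 sets of at least 1 progeny are equally likely, the chance of so many loci on a single set is at most 5.85e-05 by the pair mean. By the rule on each array it is at most 0.000996, just under the limit set for the test. The gap of 0.25 was chosen after the data had been seen, and it left out dam regions with other carriers. Among these were the losses on chromosome 4 from 114577739, shared with progeny 6, and on chromosome 9 from 109568596, shared with progeny 1 and progeny 4. The chance holds only for the regions so selected. Independent transmission of autosomal alleles is therefore not excluded as the cause of this sharing. The 4 such regions of the sire had 4 different sets of carriers by the pair mean. Sequence shared with the X or Y chromosome stays open, since in 5 of the 7 regions by the pair mean, and 4 of 5 by the rule on each array, the carriers were exactly the animals with an X median over 0.5. Probe sequences were not used.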

How the results depend on the processing

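No difference in segment count between progeny and parents was called under any alternative. Without the sire, without the dam, or with progeny 1 and progeny 4 both left out, too few splits remain for any p under 0.05, so these alternatives say nothing on whether the call is stable. The difference of 34.7 turned to -0.667 with at least 10 probes (exact permutation p = 0.643) and to -12.8 with progeny 1 and progeny 4 both left out (exact permutation p = 0.600), both chosen after the data had been seen. It ranged from 3.4 to 48.6 when each animal was left out, lowest without progeny 1. The sign of no named region reversed.

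Call counts depended on the caller's settings. Against 760 segments, the total was 141 with normexp, 2413 and 138 with breakpoint penalties of 10 and 40, 1559 and 146 with amplitude thresholds of 0.15 and 0.40, 63 and 24 with at least 5 and 10 probes, and 441 without the isolated probes called in the whole family, the last 2 added after the data had been seen. Against 459 progeny-only regions, the same settings gave 49, 1563, 58, 755, 100, 31, 2 and 261, and 168 without progeny 1 and progeny 4. Against 90 regions of a parent and progeny they gave 24, 150, 36, 393, 3, 6, 5 and 36, with 52 without progeny 1 and progeny 4 and 240 without required agreement of the arrays. Against 77 regions of parents only, normexp gave 11, the penalties 305 and 9, the thresholds 126 and 13, and at least 5 and 10 probes 5 and 0. Against 3 regions in all animals there were 1 with normexp, 9 and 1 with the thresholds, 1 with at least 5 or 10 probes, 5 without required agreement and 1 without the isolated probes. Leaving out each animal gave 274 to 507 progeny-only regions, lowest without progeny 1, 32 to 87 of a parent and progeny, lowest without the sire, 34 to 90 of parents only, lowest without the dam, and 2 to 4 in all animals. The penalties, thresholds and probe minimums act on the count by construction. Normexp added an offset of 50 to each channel, where the median background-subtracted signals of the arrays lay between 90.2 and 205. That draws log2 ratios towards 0 by construction, and how much of the fall it made was not tested. This setting also replaced the processed signals with the median spot signals, so the fall cannot be credited to the background correction alone.

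Of the X and Y medians, normexp lowered X to 0.87 in the dam, 0.87 in progeny 5 and 0.82 in progeny 6, and gave -0.048 in progeny 1, -0.026 in progeny 3 and -0.043 in progeny 4. It moved Y to -0.36 in the dam, -0.37 in progeny 5 and -0.36 in progeny 6. The offset draws ratios towards 0, and neither its share in these moves nor that of the changed input signal was tested. The arrays with the animal in Cy5 gave X medians of -0.038 in the sire, 0.95 in the dam, -0.05 in progeny 1 and 0.95 in progeny 6 and a Y median, as measured with probes not well above background included, of -3.44 in progeny 5. Those with the animal in Cy3 gave X medians of 0.016 in progeny 2, 1.00 in progeny 5 and 0.96 in progeny 6.

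Probes that differed from the reference numbered 13444 and 2425 at effect thresholds of 0.15 and 0.40 and 4004 with normexp, against 6887, and 6171 to 7251 without each animal. Lower probes outnumbered higher ones in every setting. Between progeny and parents the count was 0 to 4 without each animal, the 4 without the dam, which leaves a lone parent assumed to vary like the others, and 0 in every other setting. Of the means of named regions under other settings, 174 moved by less than their spread and 24 by more. With normexp 20 of the 33 means fell short of the threshold of 0.25, namely 1 of the 3 in all animals, 2 of the 10 in a parent and progeny, 7 of the 10 in progeny only and all 10 in parents only. The chromosome 10 gain went from 0.62 to 0.09, the chromosome 9 loss from 109568596 from -0.37 to -0.20, the chromosome 19 loss from 46794891 from -0.35 to -0.23, and the chromosome 11 loss from 96237382 from -0.44 to -0.19. The chromosome 2 stretch from 70079530, where the reference gives only a bound, had 0.70. With the running median subtracted, the chromosome 11 loss from 3083938 went from -0.37 to -0.18, the only named mean to fall short in that setting. This loss lies near the start of the chromosome, where the window is filled with copies of the first probe's value, so its fall decides nothing. The gene-level tests and gene lists were not run under any setting. No paired analysis was possible because all progeny share a single sire and a single dam. Of 80 planted losses of 3 probes at -0.40, 40 were recovered, which limits calls of few probes. Signal over noise was lowest, at 35.2, in the reference channel of an array of progeny 4, and its part in the calls was not tested.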

Other observations

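The tests in this part were chosen after the data had been seen. Regions whose carriers stood at least 0.25 apart from every other animal were counted as a description. There were 119 with carriers among the progeny and in neither parent, and the difference profiles, which hold no copy number signal, gave 125. In 112 of the 119 a single animal was the carrier. Of the 119, 6 had 5 or more probes, beside 3 in the difference profiles. Regions shared by the sire and progeny numbered 4, and those shared by the dam and progeny numbered 7.

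Among the 6 regions of 5 or more probes found only in progeny were the 2 chromosome 11 regions and the chromosome 7 region named above, a 5-probe loss on chromosome 4 from 73009887 to 73017549 at -0.54 in progeny 4, with the other animals between -0.11 and 0.03, and a 5-probe loss on chromosome 3 from 35070153 to 35078657 at -0.36 in progeny 1, with the others between -0.10 and 0.13. A 5-probe loss on chromosome 8 from 114677950 to 114686912 averaged -0.33 in progeny 3 and progeny 4, with the others between -0.02 and 0.08. These were picked out after their values were seen.

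Before averaging, the animal-over-reference values of the 2 arrays of an animal correlated between -0.368 and -0.190 across autosomal probes. The probes on the unplaced contigs had medians between -0.05 and 0.03 in the 8 animals.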
